A study of Homo sapiens with 36 samples.

How the data were processed

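RNA was sequenced from human T-HESC cells, an hTERT-immortalized line of endometrial stromal fibroblasts, 48 h after transfection with 50 nM siRNA. The labels describe 36 samples in 6 groups: siRNA against DRAP1, ESRRA, PPARD or YY1, and 2 groups with non-targeting control siRNA, called Ctrl1 and Ctrl2. Each group held 3 libraries, and each of the 18 libraries was sequenced in 2 runs, which were read as repeats of 1 library and not as replicates. Per the labels, Ctrl1 was the control for DRAP1 and ESRRA and Ctrl2 the control for PPARD and YY1. Libraries were stranded total RNA depleted of ribosomal RNA, read from a single end over 50 bases, and the labels state that only knockdowns above 70% by quantitative PCR were sequenced.

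The values came from 4 tables, 1 per knockdown, each holding the authors' own comparison of a knockdown with its control per transcript. Per the file headers, the authors' deposited tables hold a mean normalized count over the libraries of the comparison (unit: signal), which is not scaled to a fixed library size. The authors' log2 fold change and its standard error were in log2 units, with negative values where the knockdown was lower. Per the file headers the authors also gave a Wald statistic, used here as a score, and a p-value with its adjusted value. The submitters' processing notes name HISAT2 2.1.0, StringTie 1.3.6, DESeq2 2.11.40.6, edgeR, limma and the genome build hg38, without their roles or order. The annotation release and the counting step used by the authors were not given in the sources used here. No values per library were analysed here, so the depth of each library is unknown, no count of 0 could be given its limit, and spread between replicates entered only through the authors' standard errors. Sums of the mean normalized counts, divided by 10 to the power of 6, were 5.12 in the DRAP1 and ESRRA tables, 5.13 in the PPARD table and 5.14 in the YY1 table. Whether the authors merged the 2 runs of a library before testing was not given in the sources used here. 0 columns of other samples were used.

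Each table listed 100454 transcript identifiers. Identifiers were matched without their version to GENCODE release 29, which gave symbols and GRCh38 coordinates (counted from 1). Of all identifiers 82.7% matched, and of those with an adjusted p 94.4% in the DRAP1 table and 94.5% in the other tables. The level in each group was calculated from the mean normalized count and the fold change, taking both groups to hold equal numbers of libraries. Where a group lay under 1 normalized count, the fold change is a fitted value and sets no bound. The total of a gene was the sum over its transcripts, and 0.5 was added to each total before taking its log2 ratio.

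A transcript was called when the adjusted p in the authors' deposited table was under 0.05. Tests, named genes, gene lists and the alternatives described as planned were fixed before the data were examined. The named genes were the targeted gene, the 10 highest and 10 lowest log2 fold changes among called transcripts with a mean normalized count of 100 or more and a gene symbol, and up to 4 members with the smallest adjusted p from each list past its test. After the values were seen, a view restricted to main transcripts was added, meaning those with 80% or more of their gene's count in both groups, and the 10 highest and 10 lowest of these were named as well.

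Of the 38 gene lists fixed, 36 had 5 or more measured members in each knockdown and were tested, each gene standing by its transcript with the highest mean normalized count. The lists with fewer, markers of endothelial and of immune cells, were not tested. The test was cameraPR of limma 3.58.1 on the Wald statistics in the authors' deposited tables (competitive, two-sided, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 36 lists of a knockdown. A correlation between genes could not be estimated without values per library, so no call was checked against an estimated correlation. Members were also counted after the p-values were adjusted over the list alone.

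Pairs of knockdowns were compared by Pearson correlation of log2 fold changes across transcripts with a mean normalized count of 50 or more in both tables. For pairs with 1 control in common, 100 simulations with no effect, in which the control carried an equal share of each error variance, gave the value that the shared control alone would produce. Calls shared by a pair were set against the number expected if calls fell independently.

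For the closing section, the presence of every word of 7 bases in annotated 3′ UTRs of 30 bases or more was tested against the log2 fold change of main transcripts of coding genes with a mean normalized count of 50 or more. Fold changes were limited to 2 in either direction, the regression included length and GC content, words in 30 or more genes were kept, and 100 shuffles of the fold changes over genes gave the range to be found with no association. Transcript swaps were counted as transcripts with 100 or more normalized counts in 1 group that lay 16-fold or more apart between groups while the total of their gene differed by under 1.5-fold.

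Calls, lists, the shared response and the word search were tested on simulated data, and the counts of swaps were not. For calls, 200 transcripts of each table were given a known change. They were drawn from, and adjusted over, only transcripts with a mean normalized count of 100 or more (6809, 6835, 6808 and 6791). The median over all transcripts with an adjusted p was 34.9 to 41.3, so recovery at lower counts was not tested. A 2-fold change was recovered for 136 of 200 with the standard errors of the DRAP1 table, 117 with ESRRA, 121 with PPARD and 123 with YY1. A 1.5-fold change was recovered for 62, 51, 59 and 56 of 200 in the same order. False calls made up 3.55%, 2.50%, 1.63% and 6.82% of calls at 2-fold and 4.62%, 12.1%, 1.67% and 8.20% at 1.5-fold. A shift of 1 in the Wald statistics of a list was recovered for 32, 12, 16 and 10 of 36 lists, a downward shift of 2 for 36, 35, 36 and 35, and shuffled statistics gave a call in 1, 1, 0 and 2 of 36 runs. Shuffling over genes removes any correlation between the members of a list, so these runs could not test false calls that arise from it. The simulated shared response returned 103% of the covariance put in. In the word search, a word lowered in shuffled changes came back at rank 1 in each of the 4 knockdowns.

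The alternatives fixed beforehand were other adjusted p thresholds, a floor on the fold change, other filters on low counts, standard errors multiplied by the square root of 2, an empirical null, centring, a preset correlation of 0.05, ranks, and other statistics for the pairs. Alternatives chosen after the data were seen were main transcripts, transcripts with 1 or more normalized counts in both groups, genes without a 3′ UTR word, and a list without MT-ND4. A replicate block, leaving out 1 replicate, another normalization and other splits of the samples needed values per library and were not run. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.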

Results

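Gene expression was measured by RNA sequencing in T-HESC cells, an immortalized line of human endometrial stromal fibroblasts, after siRNA against 1 of 4 transcription regulators. The series title places the work in a study of how expression gained in eutherian mammals relates to decidualization, the change of these fibroblasts into the secretory cells that support pregnancy. Each comparison asked which transcripts depended on the targeted factor in cells kept in maintenance medium. There were 3 libraries in each of the 6 groups, with Ctrl1 compared with the DRAP1 and ESRRA knockdowns and Ctrl2 with the PPARD and YY1 knockdowns. The authors' deposited tables gave adjusted p-values for 20364 transcripts in the DRAP1 comparison, 19659 for ESRRA, 20010 for PPARD and 20013 for YY1. All fold changes below are log2 values of knockdown over control with the authors' standard error (SE), and p-values rest on these SEs. They measure spread between these libraries only if the 2 runs of each library were merged before testing, which the sources used here did not state, so standard errors multiplied by the square root of 2 were also tried. How many libraries showed each direction could not be read from the tables, and group levels were calculated from the mean and the fold change.

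Each targeted gene fell in its own knockdown. For DRAP1, the authors' deposited table gave -10.37 (SE 1.11, adjusted p = 2.39e-17) for transcript DRAP1-208 (ENST00000532933, chromosome 11, 65919724 to 65921554, GRCh38), while DRAP1-201 at -1.57 was not called (adjusted p = 0.0800) and the total of the gene changed by -3.88. ESRRA-203 (ENST00000406310, chromosome 11, 64305572 to 64316738) changed by -3.39 (SE 0.92, adjusted p = 0.00882) in the authors' deposited table, from 62.0 to 5.90 normalized counts. For PPARD, 2 transcripts fell in the authors' deposited table, PPARD-201 (ENST00000311565, chromosome 6, 35342614 to 35428178) by -2.14 (SE 0.44, adjusted p = 6.88e-05) and PPARD-202 by -3.93 (SE 1.04, adjusted p = 0.00675). PPARD-202 went from 18.2 to 1.19 normalized counts, and the total of the PPARD gene changed by -2.49. YY1-201 (ENST00000262238, chromosome 14, 100238985 to 100282792) changed by -3.59 (SE 0.39, adjusted p = 3.41e-17) in the authors' deposited table, from 583 to 48.3 normalized counts. In the other knockdowns the transcripts of these genes were not called, except PPARD-202 in the YY1 knockdown, which the authors' deposited table gave as -5.99 (SE 1.21, adjusted p = 5.47e-05) while the total of the PPARD gene changed by 0.15. With standard errors multiplied by the square root of 2, the fall of ESRRA was no longer called (adjusted p = 0.348).

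**Figure D1:**
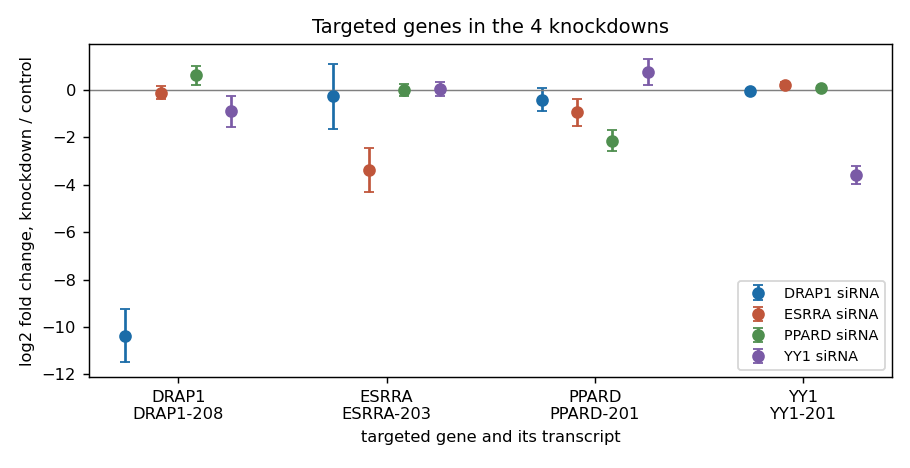
Log2 fold change of the transcripts of the 4 targeted genes (vertical axis) in each knockdown, with bars for the standard error in the authors' deposited tables. YY1-201 sat at -3.59 in the YY1 knockdown, and between -0.06 and 0.20 in the others.

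In the DRAP1 knockdown, genes of mitosis and DNA replication and replication-dependent histone genes lay higher as groups, and contractile, endoplasmic reticulum (ER) chaperone and WNT signalling genes lay lower. DRAP1 is a subunit of the NC2 complex, which represses transcription through the TATA-binding protein. The mitotic kinesin KIF11 rose by 0.71 (SE 0.16, adjusted p = 0.00142), the kinase AURKB by 1.10 (SE 0.27, adjusted p = 0.00473) and the topoisomerase TOP2A by 0.67 (SE 0.17, adjusted p = 0.00631) in the authors' deposited table. The ER chaperone calnexin (CANX) changed by -0.44 (SE 0.038, adjusted p = 9.89e-27) in the authors' deposited table, and the actin-binding gene CALD1 by -0.39 (SE 0.072, adjusted p = 1.83e-05). ACTA2, smooth muscle actin, changed by -0.33 (SE 0.073, adjusted p = 0.000982) in the authors' deposited table.

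Of 36 genes of the G2 and M phases measured in the DRAP1 knockdown, 3 rose, 0 fell and 33 were not called, 3 were called when adjusted over the list alone, and the list test gave adjusted p = 1.64e-08. None of 36 replication-dependent histone genes was called over all transcripts, but 33 had positive values, 2 (H2BC9 at 0.51 and H1-4 at 0.43 in the authors' deposited table) passed adjusted over the list alone, and the list moved up (adjusted p = 4.41e-08). Among 33 S phase genes 0 rose, 0 fell and 33 were not called, 1 (MCM4, 0.30 in the authors' deposited table) was called adjusted over the list alone, and the list moved up (adjusted p = 0.00517). ER chaperone and unfolded protein genes numbered 19, of which 0 rose, 1 fell (CANX) and 18 were not called, with 1 adjusted over the list alone, and the list moved down (adjusted p = 9.02e-05). WNT signalling had 21 members, of which 0 rose, 2 fell and 19 were not called, with 3 adjusted over the list alone and a list adjusted p of 9.63e-05. These were WNT2 at -0.40 (SE 0.072) and CTNNB1 at -1.07 (SE 0.12) in the authors' deposited table, though the total of CTNNB1 over its transcripts changed by 0.20. For 14 contractile genes of smooth muscle, 0 rose, 2 fell (CALD1 and ACTA2) and 12 were not called, 2 were called adjusted over the list alone, and the list adjusted p was 0.00395.

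The DRAP1 comparison had 261 calls, 126 higher and 135 lower, of which 97 were main transcripts with 80% or more of their gene's count in both groups. The main transcripts named here and below were chosen after the values were seen, and their order is that among called ones with a mean normalized count of 100 or more. The lowest included SUCO at -1.29 (SE 0.20), GPR107 at -1.06 (SE 0.19) and PTGFR, a prostaglandin receptor, at -0.96 (SE 0.16) in the authors' deposited table. ACAT2 at -0.73 (SE 0.16), PANK3, which starts coenzyme A synthesis, at -0.70 (SE 0.089) and TGM2, a transglutaminase, at -0.67 (SE 0.19) were also among the 10 lowest in the authors' deposited table. MRPL27, a mitochondrial ribosomal protein gene, was highest at 1.62 (SE 0.17, adjusted p = 9.46e-19) in the authors' deposited table. TXNIP, an inhibitor of thioredoxin, at 0.88 (SE 0.12), HMGB2 at 0.80 (SE 0.22), FANCD2 of DNA repair at 0.81 (SE 0.21) and DICER1, which cuts microRNA precursors, at 0.73 (SE 0.14) were also among the 10 highest in the authors' deposited table. Of the 20 transcripts named by size, 12 traded places with a called partner of their gene, such as PFKP-202 at -11.26 (SE 1.09) with PFKP-203 at 10.36 (SE 1.40), and RGS4-204 at -10.54 (SE 1.12) with RGS4-203 at 10.80 (SE 1.10) in the authors' deposited table. The totals of PFKP and RGS4 changed by 0.22 and 0.24. The list of the general transcription machinery, to which DRAP1 belongs, was not called (44 members, 0 higher, 2 lower, 42 not called, 2 adjusted over the list alone, adjusted p = 0.373), with a median of 0.01, a mean of -0.30 and a test direction that was down. The targeted gene DRAP1, at -10.37, was 1 of the lower members and weighed on the mean and the direction. Of the 261 calls, 122 had 1 group under 1 normalized count, and 92 calls were made with standard errors multiplied by the square root of 2. The S phase list gave adjusted p = 0.105 at a preset correlation of 0.05, and by ranks the contractile list gave 0.147 and the WNT list 0.0549.

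After the ESRRA knockdown, contractile and WNT genes lay lower as groups, though neither list stayed called by ranks of the statistics. ESRRA is an orphan nuclear receptor known for its role in mitochondrial metabolism. MT-ND4, a complex I subunit encoded by the mitochondrial genome, had the largest fall among main transcripts with a mean normalized count of 100 or more, -4.90 (SE 0.27, adjusted p = 2.06e-68), from 678 to 22.7 normalized counts in the authors' deposited table. ACTA2 changed by -1.11 (SE 0.072, adjusted p = 2.04e-50), the growth factor FGF1 by -2.20 (SE 0.20, adjusted p = 2.23e-25) and the WNT antagonist DKK1 by -0.98 (SE 0.12, adjusted p = 9.22e-14) in the authors' deposited table. The chromatin protein HMGA2 rose by 1.64 (SE 0.17, adjusted p = 8.11e-19) and DICER1 by 1.40 (SE 0.12, adjusted p = 6.16e-30) in the authors' deposited table.

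Of 14 contractile genes in the ESRRA knockdown, 0 rose, 3 fell (ACTA2, CALD1 and ACTG2) and 11 were not called, 6 were called adjusted over the list alone (5 lower), and the list adjusted p was 0.00025. CALD1 changed by -2.26 (SE 0.51) and ACTG2 by -1.30 (SE 0.35) in the authors' deposited table, and the CALD1 transcript carried the 3′ UTR word described below. WNT signalling had 21 members, with 0 higher, 4 lower and 17 not called, 6 adjusted over the list alone (5 lower) and a list adjusted p of 0.002. Besides DKK1, the 4 were WNT2 at -0.57 (SE 0.075), WNT5A at -1.45 (SE 0.44) and CTNNB1 at -0.88 (SE 0.21) in the authors' deposited table, the total of CTNNB1 changing by -0.04. Among 13 mitochondrially encoded genes, 0 rose, 1 fell and 12 were not called, 1 was called adjusted over the list alone, and the list adjusted p was 0.000135. That call rested on MT-ND4, since without it the other 12 members gave adjusted p = 0.308 and a median of -0.45. Nuclear genes of oxidative phosphorylation were not called as a list (75 members, 0 higher, 2 lower, 73 not called, 1 adjusted over the list alone, adjusted p = 0.242). Nor was the list of ESRRA and PGC1 targets and partners (12 members, 0 higher, 1 lower, 11 not called, 1 adjusted over the list alone, adjusted p = 0.806), whose called member was ESRRA and whose median of 0.07 and mean of -0.10 differed in sign, the test direction being down.

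There were 803 calls in the ESRRA comparison, 368 higher and 435 lower, and 581 of them were main transcripts (256 higher and 325 lower). SLC35E1 at -3.60 (SE 0.27), STARD3NL at -2.62 (SE 0.27), UXT at -2.57 (SE 0.37) and ATP6V1F, a subunit of the lysosomal proton pump, at -2.26 (SE 0.26) followed MT-ND4 above that count in the authors' deposited table. PODXL at 1.64 (SE 0.21), MAMDC2 at 1.49 (SE 0.28), the gastrin-releasing peptide receptor GRPR at 1.34 (SE 0.19), the integrin ITGA3 at 1.32 (SE 0.22) and G0S2, an inhibitor of lipolysis, at 1.22 (SE 0.23) were among the highest in the authors' deposited table. Trades within a gene included DDX6-208 at -11.60 (SE 1.17) with DDX6-206 at 11.71 (SE 1.09), and EIF5A-202 at -9.48 (SE 0.80) with EIF5A-205 at 11.67 (SE 1.09) in the authors' deposited table, with gene totals changed by 0.05 and 0.26. EIF2S1-201 at 10.88 (SE 1.09), RTN3-208 at -10.23 (SE 1.16) and AAMP-202 at -7.32 (SE 0.79) in the authors' deposited table moved with their gene totals, which changed by 1.31, -1.73 and -1.94. With standard errors multiplied by the square root of 2, 267 transcripts were called, and a floor of 1 on the absolute log2 value left 366. By ranks these 3 lists lost their call, with adjusted p of 0.133 for contractile, 0.0608 for WNT and 0.0553 for mitochondrially encoded genes, while 3 others gained one: histones (higher, 0.00350), G2 and M phase (higher, 0.0358) and ER chaperones (lower, 0.0349).

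Knockdown of PPARD, a nuclear receptor for fatty acids, was followed by lower groups of amino acid stress (ATF4), cytosolic ribosomal protein, contractile and TGF-β response genes and by higher groups of G2 and M phase and p53 target genes, of which 1 list, ATF4, stayed called at a preset correlation of 0.05. The stress factor NUPR1 changed by -0.64 (SE 0.090, adjusted p = 1.59e-10), the mitochondrial folate enzyme ALDH1L2 by -1.30 (SE 0.25, adjusted p = 1.43e-05) and the glycyl-tRNA synthetase GARS1 by -0.59 (SE 0.14, adjusted p = 0.00111) in the authors' deposited table. SERPINE1, the inhibitor of plasminogen activation, changed by -1.48 (SE 0.11, adjusted p = 9.96e-35) and ACTA2 by -0.81 (SE 0.092, adjusted p = 5.10e-16) in the authors' deposited table. BTG2, an antiproliferative p53 target, rose by 2.12 (SE 0.41, adjusted p = 2.43e-05) and the receptor tyrosine kinase KIT by 2.15 (SE 0.30, adjusted p = 1.06e-10) in the authors' deposited table.

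The ATF4 list had 28 members in the PPARD knockdown, of which 0 rose, 6 fell and 22 were not called, with 8 adjusted over the list alone and adjusted p = 4.85e-06. Besides those above, XPOT, which exports tRNA, fell (-0.54, SE 0.12, in the authors' deposited table). Of 74 cytosolic ribosomal protein genes, 1 rose, 6 fell and 67 were not called, 14 were called adjusted over the list alone (13 lower), and the list adjusted p was 0.000133. RPS12 at -0.65 (SE 0.11), RPL13A at -0.42 (SE 0.075) and RPS8 at -0.42 (SE 0.089) fell in the authors' deposited table. The transcript that rose was RPL23A-204 at 10.63 (SE 1.09) in the authors' deposited table, while the total of RPL23A changed by 0.45. None of 36 G2 and M phase genes was called over all transcripts or adjusted over the list alone (0 higher, 0 lower, 36 not called), yet 32 were positive, the median was 0.41 and the list adjusted p was 0.000609. TOP2A at 0.57 (SE 0.20, adjusted p = 0.102) and HMMR at 0.56 (SE 0.21) in the authors' deposited table were examples. Of 25 p53 targets, 3 rose (BTG2, TIGAR and PPM1D), 0 fell and 22 were not called, 4 were called adjusted over the list alone, and the list adjusted p was 0.0301. TIGAR was at 0.59 (SE 0.18) and PPM1D at 0.57 (SE 0.18) in the authors' deposited table. TGF-β response genes numbered 21, with 0 higher, 2 lower (SERPINE1 and INHBA, the latter -0.51 with SE 0.12 in the authors' deposited table) and 19 not called, 2 adjusted over the list alone and adjusted p = 0.0498 (0.700 without genes carrying the 3′ UTR word described below). The 14 contractile genes had 0 higher, 1 lower (ACTA2) and 13 not called, 2 adjusted over the list alone and adjusted p = 0.0498. PPAR targets were not called as a list (19 members, 1 higher, 1 lower, 17 not called, 2 adjusted over the list alone, adjusted p = 0.547). Their called members were ANGPTL4 at 2.94 (mean of 9.70 normalized counts) and ACSL1, which carried the word, at -1.10 in the authors' deposited table. Fatty acid oxidation gave the same adjusted p (24 members, 0 higher, 1 lower, 23 not called, 1 adjusted over the list alone, adjusted p = 0.547).

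The PPARD comparison had 737 calls, 300 higher and 437 lower, with 516 main transcripts (185 higher and 331 lower). Below the others lay the long non-coding RNA SNHG16 at -2.48 (SE 0.55), the kinase UHMK1 at -2.43 (SE 0.14, adjusted p = 6.45e-61), the phosphatase PTPN11 at -2.33 (SE 0.20), the centriole gene CETN2 at -2.06 (SE 0.16) and HACD3, an enzyme of fatty acid elongation, at -2.01 (SE 0.14) in the authors' deposited table. The RNA-binding gene IGF2BP3 at 2.87 (SE 0.46), MAMDC2 at 1.51 (SE 0.29), DICER1 at 1.49 (SE 0.098), TMEM245 at 1.34 (SE 0.095) and HMGA2 at 1.27 (SE 0.17) were among the highest in the authors' deposited table. EIF3F-208 stood at 9.52 (SE 1.10) in the authors' deposited table, from 0.338 to 249 normalized counts. Trades within a gene included DDX6-206 at -11.91 (SE 1.09) with DDX6-208 at 11.26 (SE 1.18), the reverse of the ESRRA knockdown, and EMP3-201 at -11.20 (SE 1.09) with EMP3-206 at 9.50 (SE 0.84) in the authors' deposited table, with gene totals changed by -0.38 and -0.23. With standard errors multiplied by the square root of 2 there were 265 calls, at an adjusted p under 0.01 there were 487, and with a floor of 1 on the absolute log2 value 350. At a preset correlation of 0.05 the adjusted p was 0.208 for the contractile and p53 lists, 0.0744 for ribosomal protein and G2 and M phase genes and 0.229 for TGF-β response. By ranks it was 0.134 for contractile, 0.0565 for p53 and 0.524 for TGF-β response genes, and at a mean normalized count of 50 or more 0.0959 for contractile and 0.0540 for TGF-β response genes.

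In the YY1 knockdown, genes of cholesterol synthesis and oxidative phosphorylation lay lower as groups, and genes of the NRF2 and ATF4 stress responses, DNA replication, mitosis and replication-dependent histones lay higher. Of these, 3 lists, cholesterol synthesis, NRF2 and ATF4, stayed called at a preset correlation of 0.05. YY1 is a zinc finger factor that activates or represses transcription. In the authors' deposited table HMGCR, the rate-limiting enzyme of cholesterol synthesis, changed by -0.79 (SE 0.083, adjusted p = 1.47e-18), CYP51A1 by -0.78 (SE 0.072, adjusted p = 6.87e-24) and MSMO1 by -1.07 (SE 0.11, adjusted p = 2.56e-19). GCLM, which takes part in glutathione synthesis, rose by 1.05 (SE 0.21, adjusted p = 5.65e-05) and the haem oxygenase HMOX1 by 1.20 (SE 0.36, adjusted p = 0.0230) in the authors' deposited table. The secreted hormone STC2 rose by 0.73 (SE 0.11, adjusted p = 2.97e-09) and the pseudokinase TRIB3 by 1.11 (SE 0.24, adjusted p = 0.000344) in the authors' deposited table.

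Of 25 cholesterol synthesis genes in the YY1 knockdown, 0 rose, 6 fell and 19 were not called, 7 were called adjusted over the list alone, and the list adjusted p was 3.66e-08. DHCR24, the last of the 4 named, was at -0.44 (SE 0.085) in the authors' deposited table. Oxidative phosphorylation had 75 members, with 0 higher, 9 lower and 66 not called, 14 adjusted over the list alone and adjusted p = 0.000187. NDUFA5 at -1.49 (SE 0.24), ATP5F1A at -0.78 (SE 0.16) and SDHD at -0.64 (SE 0.12) fell in the authors' deposited table, whereas NDUFB3 at -9.22 (SE 1.09) stood beside a gene total changed by only -0.19. The ATF4 list, which was lower in the PPARD knockdown, had 28 members here, of which 8 rose, 0 fell and 20 were not called, with 11 adjusted over the list alone (9 higher) and adjusted p = 0.000187. DDIT4 at 0.64 (SE 0.15) and the lipoprotein receptor VLDLR at 2.77 (SE 0.66) in the authors' deposited table were among them. The difference between the PPARD and YY1 knockdowns was not tested. NRF2 targets numbered 21, of which 5 rose, 0 fell and 16 were not called, 6 passed adjusted over the list alone, all 21 were positive and the adjusted p was 0.000187. TXNRD1 was at 0.75 (SE 0.24) in the authors' deposited table, and AKR1B10 at 5.69 (SE 1.17) with a mean of only 7.14 normalized counts.

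Among 33 S phase genes in the YY1 knockdown 0 rose, 0 fell and 33 were not called, 5 passed adjusted over the list alone, and the list moved up (adjusted p = 0.000901). GINS2 at 0.91 (SE 0.31), CLSPN at 0.45 (SE 0.15), MCM2 at 0.92 (SE 0.33) and CHAF1B at 0.84 (SE 0.30) in the authors' deposited table were its examples, none of them called over all transcripts. Of 36 G2 and M phase genes 3 rose, 0 fell and 33 were not called, 4 were called adjusted over the list alone, and the list adjusted p was 0.0129. TPX2 at 0.57 (SE 0.18) and ANLN at 0.48 (SE 0.16) rose in the authors' deposited table, as did an AURKA transcript at 5.11 (adjusted p = 0.0155) whose gene total changed by 0.42. The 36 histone genes were all positive, with 0 called over all transcripts or adjusted over the list alone (36 not called), a median of 0.26 and a list adjusted p of 0.00485. The list of polycomb proteins and YY1 partners was not called (25 members, 1 higher, 2 lower, 22 not called, 3 adjusted over the list alone, adjusted p = 0.916), its median of 0.06 and mean of -0.07 differing in sign and the test direction being down. YY1 itself was 1 of the lower members, with CBX4 at -1.18, and EZH2, which methylates histone H3, was the higher one at 1.18 in the authors' deposited table.

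YY1 knockdown gave 1037 calls, 442 higher and 595 lower, of which 802 were main transcripts (326 higher and 476 lower). CYB5B, a cytochrome b5 of the mitochondrial outer membrane, was at -3.71 (SE 0.17, adjusted p = 6.31e-96), NIPSNAP1 at -1.84 (SE 0.27), TMEM119 at -1.83 (SE 0.20), the WNT receptor FZD6 at -1.79 (SE 0.23) and SUMF1 at -1.78 (SE 0.27) in the authors' deposited table. TXNDC5 was given as -9.31 (SE 1.66) in the authors' deposited table, and it overlaps the read-through gene BLOC1S5-TXNDC5. HYOU1, an ER chaperone, at 2.37 (SE 0.75), PODXL at 1.67 (SE 0.31), the DNA demethylase TET3 at 1.55 (SE 0.37), the metalloprotease PAPPA2 at 1.37 (SE 0.22) and SLC7A5, an amino acid transporter, at 1.33 (SE 0.38) were among the highest in the authors' deposited table. Trades within a gene included EMP3-201 at -11.17 (SE 1.09) with EMP3-206 at 9.47 (SE 0.84), and KMT5A-201 at -9.58 (SE 1.09) with KMT5A-202 at 9.86 (SE 1.11) in the authors' deposited table, with gene totals changed by -0.26 and 0.36. With standard errors multiplied by the square root of 2 there were 316 calls, with an empirical null 547, at an adjusted p under 0.01 there were 690, and with a floor of 1 on the absolute log2 value 479. At a preset correlation of 0.05 the adjusted p was 0.0685 for oxidative phosphorylation, 0.0562 for S phase, 0.176 for G2 and M phase and 0.113 for histone genes.

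**Figure D2:**
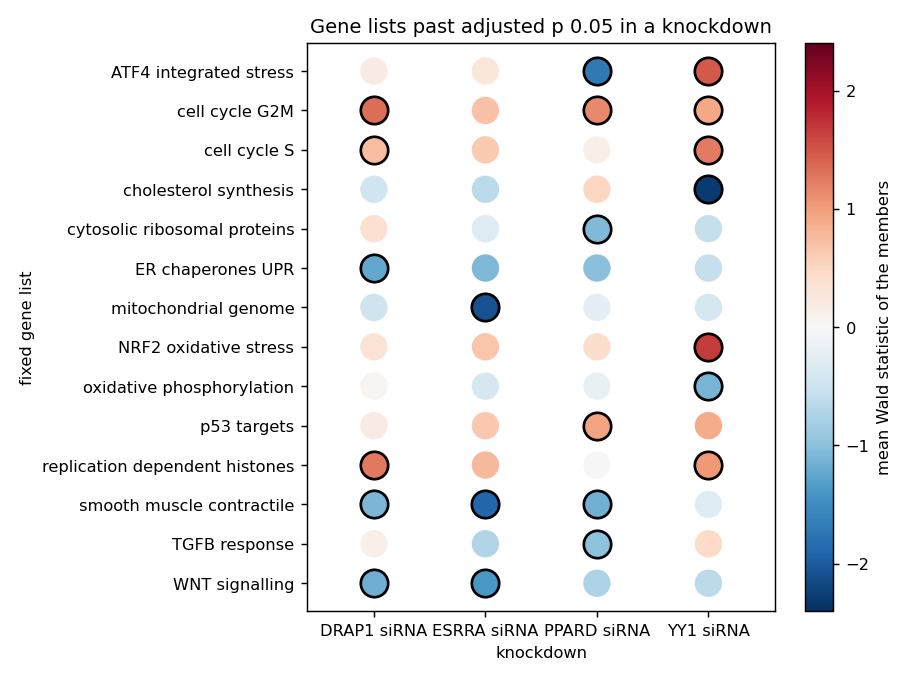
Mean Wald statistic (colour, no unit) of the members of each gene list called in a knockdown (vertical axis) in the 4 knockdowns (horizontal axis), with a black ring where the list's adjusted p was under 0.05. The statistic was lowest for cholesterol synthesis in the YY1 knockdown, at -2.30, and highest for NRF2 targets in the same knockdown, at 1.68.

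Decidualization genes were not called as a list in any knockdown of these cells, which were kept in maintenance medium. A moderate shift could have been missed, since a simulated shift of 1 in the Wald statistics was recovered for 32, 12, 16 and 10 of 36 lists (DRAP1, ESRRA, PPARD, YY1). The adjusted p was 0.589 in the DRAP1 knockdown (25 members, 1 higher, 0 lower, 24 not called, 1 adjusted over the list alone) and 0.457 in the ESRRA knockdown (26 members, 0 higher, 2 lower, 24 not called, 2 adjusted over the list alone). It was 0.379 in the PPARD knockdown (25 members, 0 higher, 2 lower, 23 not called, 3 adjusted over the list alone) and 0.472 in the YY1 knockdown (26 members, 0 higher, 2 lower, 24 not called, 2 adjusted over the list alone), where the median of 0.04 and mean of -0.02 differed in sign and the test direction was down. Single members did fall. The progesterone receptor PGR was at -0.86 (SE 0.22, adjusted p = 0.00548) in the PPARD knockdown, the growth factor BMP2 at -2.07 (SE 0.37, adjusted p = 2.07e-06) and the homeobox gene HOXA11 at -0.65 (SE 0.17, adjusted p = 0.00487) in the YY1 knockdown, as the authors' deposited tables give them. These 3 genes were chosen after their values were seen, and PGR and BMP2 carried the 3′ UTR word of their knockdown.

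Over all transcripts, fold changes were most alike between knockdowns compared with the same control. Across 8617 transcripts r was 0.539 for DRAP1 and ESRRA, against 0.459 in simulations with no effect and the control in common, and the covariance was 0.325 against 0.236. PPARD and YY1 gave r = 0.455 across 8505 transcripts, against 0.455 simulated, and a covariance of 0.325 against 0.232. Pairs with different controls gave 0.024 for DRAP1 and PPARD, 0.056 for DRAP1 and YY1, 0.109 for ESRRA and PPARD and 0.052 for ESRRA and YY1, where 0 corresponds to no shared response. Transcripts within a comparison are not independent replicates, so no p is given for these 6 correlations. Restricted to main transcripts, ESRRA and PPARD gave r = 0.305, and 48 main transcripts rose in both against 5.20 if calls were independent, with 63 against 13.1 lower in both. HMGA2, for example, was higher in both, as were TMEM245, MAMDC2 and DICER1. Main transcripts called in opposite directions numbered 13 for this pair. The other pairs with different controls also lay above independence. DRAP1 and PPARD shared 8 higher against 0.89 and 10 lower against 1.66, with 4 opposite. DRAP1 and YY1 shared 10 against 1.46 and 7 against 2.29, with 4 opposite. ESRRA and YY1 shared 28 against 8.78 and 32 against 17.4, with 39 opposite. For pairs with 1 control the main transcripts gave 0.361 (DRAP1 and ESRRA) and 0.210 (PPARD and YY1), both under the simulated 0.449 and 0.459, with covariances of 0.0390 and 0.0359 also under the simulated 0.0535 and 0.0519. With measured values below those simulated, the simulation, which assumed that the control carried an equal share of each error variance, gave no firm baseline for these pairs on main or on all transcripts, and whether they shared a response was left undecided. PPARD and YY1 thus lay below ESRRA and PPARD on main transcripts, as they did with Wald statistics (0.183 against 0.308).

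Some genes had transcripts called in opposite directions. They numbered 22 of 230 genes called in the DRAP1 comparison, 24 of 748 for ESRRA, 21 of 683 for PPARD and 26 of 983 for YY1. Of the 20 transcripts named by size in each comparison, 12, 10, 8 and 10 had a called partner of the opposite sign in that order, and 17, 13, 18 and 19 belonged to genes whose total differed by under 1.5-fold. Swaps of 16-fold or more with a steady gene total numbered 71, 80, 83 and 73 between knockdown and control. Between the 2 control groups, taken from separate tables, they numbered 313 to 331, and between 2 tables with the same control libraries 3 (Ctrl1) and 5 (Ctrl2).

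**Figure D3:**
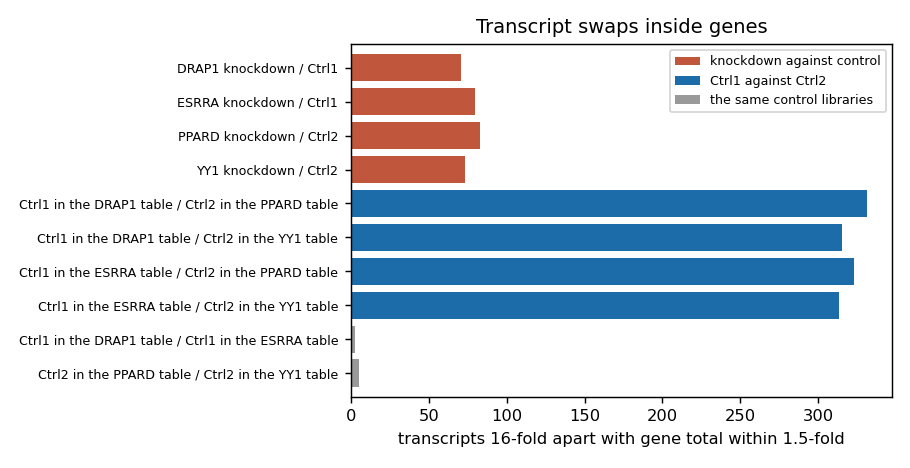
Number of transcripts 16-fold or more apart between groups while the total of their gene differed by under 1.5-fold (horizontal axis, from 0). Knockdown against control gave 71 to 83, and Ctrl1 against Ctrl2 gave 313 to 331.

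Lower transcripts shared short words in their 3′ UTRs, a different word in each knockdown. The word most strongly associated with lower values was GAACGAA for DRAP1, GAGCCTG for ESRRA, GAGCCTA for PPARD and AGAGTTC for YY1. In the ESRRA knockdown 163 of 287 lower main transcripts (56.8%) carried the word or its partner shifted by 1 base, against 24.4% of uncalled ones. The shares were 41.7% against 5.11% for DRAP1, 47.8% against 11.8% for PPARD and 45.2% against 20.7% for YY1. Among higher main transcripts the shares were 0% for DRAP1, 28.3% for ESRRA (64 of 226), 10.7% for PPARD and 12.9% for YY1. The words were chosen in these same genes, and the shares were not adjusted for 3′ UTR length or GC content. For DRAP1 the partner (t of -3.89) lay within the range of the shuffles, and the word alone was in 36.1% of lower and 2.02% of uncalled main transcripts. Among the 10 lowest main transcripts named above, the word or its partner was in 5 for DRAP1 (GPR107, PTGFR and PANK3 among them), 8 for ESRRA, 9 for PPARD and 7 for YY1, and among the 10 highest in 0, 1, 1 and 2. SERPINE1, NUPR1 and ALDH1L2 in the PPARD knockdown and NDUFA5, ATP5F1A, CYP51A1 and DHCR24 in the YY1 knockdown carried it too. Without the limit on count, main transcripts with an annotated 3′ UTR that lacked it numbered 73, 322, 336 and 546 among the calls.

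**Figure D4:**
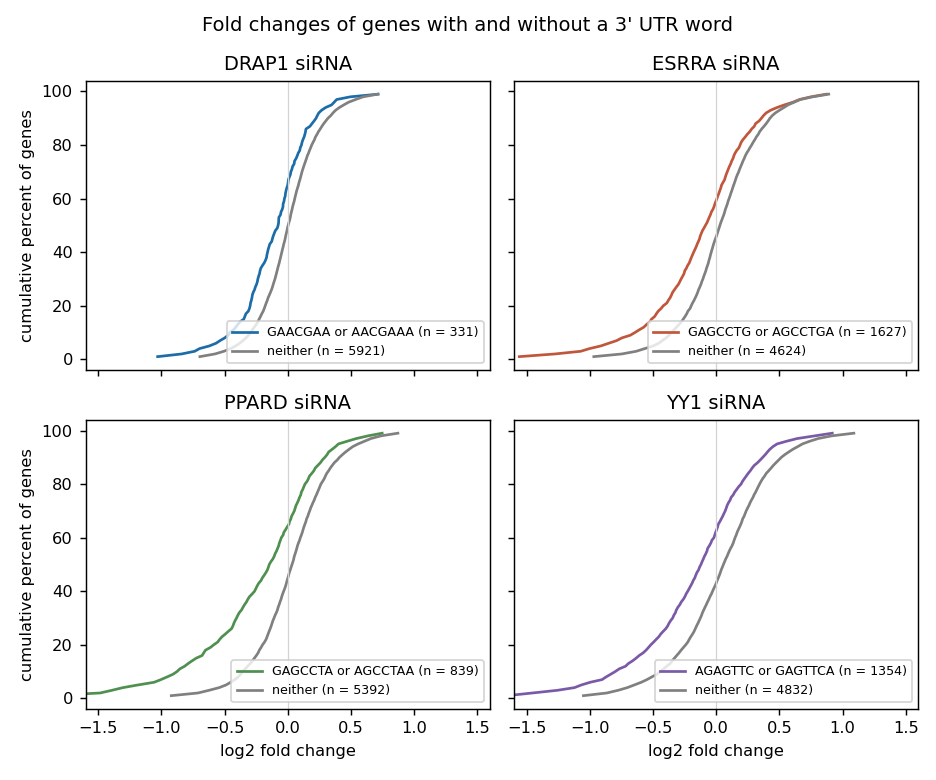
Cumulative percent of genes (vertical axis) by log2 fold change (horizontal axis) for genes whose 3′ UTR carries the knockdown's word or its shifted partner and for the other genes. Median changes with and without it were -0.08 and 0.00 for DRAP1, -0.09 and 0.03 for ESRRA, -0.15 and 0.03 for PPARD, and -0.12 and 0.06 for YY1.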

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

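Restriction to main transcripts, to transcripts with 1 or more normalized counts in both groups or to genes without a 3′ UTR word was chosen after the data were seen, as was leaving out MT-ND4, and the other settings were chosen before. No paired analysis was possible because the tables held no values per library, and for the same reason a replicate block, leaving out 1 replicate, another normalization or tool and other splits of the samples were planned but not run. The alternatives therefore test thresholds, filters and the authors' standard errors, not the authors' counting or normalization, and the depth of the libraries is unknown. With standard errors multiplied by the square root of 2, as would be needed if the 2 runs of a library had been counted as replicates, the calls numbered 92 (DRAP1), 267 (ESRRA), 265 (PPARD) and 316 (YY1), and the fall of ESRRA, -3.39, had adjusted p = 0.348 (by construction, since each Wald statistic shrank). In that setting 77 of the 80 transcripts named by size kept their call, the others being DAPK3, ZDHHC20 and EBNA1BP2. An adjusted p under 0.01 left 487 calls for PPARD and 690 for YY1, and a log2 floor of 1 left 366 (ESRRA), 350 (PPARD) and 479 (YY1), both stricter by construction. The empirical null gave 547 for YY1, 670 for ESRRA and 630 for PPARD but raised DRAP1 to 358, and the cause was not tested. Of the 261 DRAP1 calls, 97 were main transcripts, and 139 of the 261 had 1 or more normalized counts in both groups. Main transcripts whose annotated 3′ UTR lacked the word gave 73, 322, 336 and 546 calls (DRAP1, ESRRA, PPARD, YY1), with fewer transcripts tested.

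The number of lists called moved by over 1.5 times in the ESRRA knockdown to 7 on main transcripts and 5 without genes carrying the word (from 3), in the PPARD knockdown to 1 at a preset correlation of 0.05 and 3 by ranks (from 6), and in the YY1 knockdown to 3 at that correlation (from 7), the higher correlation widening the test's variance by construction. Correlations of pairs moved as follows, and the cause was not tested. DRAP1 and ESRRA gave 0.513 at a mean normalized count of 10 or more, 0.598 at 200 or more, 0.340 with Wald statistics, 0.416 with Spearman and 0.361 on main transcripts. PPARD and YY1 gave 0.434 at 200 or more, 0.183 with Wald statistics, 0.328 with Spearman and 0.210 on main transcripts. ESRRA and PPARD gave 0.0737 at 10 or more, 0.0176 at 200 or more, 0.308 with Wald statistics, 0.249 with Spearman and 0.305 on main transcripts. DRAP1 and PPARD gave 0.0921, 0.0823 and 0.0973 with Wald statistics, Spearman and main transcripts, and DRAP1 and YY1 gave 0.125, 0.09999 and 0.126. ESRRA and YY1 turned to -0.0726 at 200 or more and gave 0.0822 on main transcripts.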

Other observations

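The genes called in 3 or more knockdowns, the use of 2 overlapping words as 1 site and the setting of let-7 beside shuffles and other microRNA sites were chosen after the data were seen, and the tests of swaps, of words, of let-7 sites and of the ESRRA and PPARD pair were written down before their results were.

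Some genes were called the same way in knockdowns of factors with different functions. Among main transcripts, 19 rose and 15 fell in 3 or more knockdowns, a count for which no number expected from the shared controls was computed, although any 3 knockdowns include a pair with 1 control. DICER1 rose in all 4, by 0.73, 1.40, 1.49 and 1.31 (DRAP1, ESRRA, PPARD, YY1) in the authors' deposited tables, as did MAMDC2 by 0.83, 1.49, 1.51 and 1.42. TGM2, a transglutaminase that crosslinks matrix proteins, was at -0.67, -0.79, -1.07 and -0.50, and WNT2 at -0.40, -0.57, -0.85 and -0.66 in the authors' deposited tables, TGM2 carrying the 3′ UTR word in the ESRRA knockdown and WNT2 in the PPARD and YY1 knockdowns. In the ESRRA, PPARD and YY1 knockdowns the integrin ITGA3 rose by 1.32, 0.53 and 0.95 and the receptor MET by 0.71, 0.65 and 0.67 in the authors' deposited tables. The semaphorin SEMA7A rose by 0.79, 1.01 and 1.24 in the same knockdowns per the authors' deposited tables. SPARC, a matrix protein, rose by 0.31, 0.29 and 0.47 in the DRAP1, ESRRA and PPARD knockdowns, where ACTA2 was at -0.33, -1.11 and -0.81 in the authors' deposited tables. Error of a single control set is argued against for genes called against both sets, such as DICER1, and for the 48 main transcripts higher and 63 lower in both the ESRRA and PPARD knockdowns, which had different controls. A response common to the targeting siRNAs and an effect of the non-targeting siRNA on both control sets stay open, whereas an effect of transfection as such would be in both arms.

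Transcripts of 1 gene that traded places, such as those of DDX6 and EMP3, were most frequent between the 2 control sets, which had 4.176 times as many swaps as knockdown and control (mean 320.5 against 76.75). Switching driven by the targeted factor is argued against as the main cause, since the number of swaps differed by 1.169 times between the highest and lowest knockdown while calls of main transcripts differed by 8.27 times. Assignment of reads between transcripts of 1 gene may account for these values, and single-end reads of 50 bases often fall in exons that such transcripts share. Separate tables as such are argued against, since the same control libraries in 2 tables differed by only 3 (Ctrl1) and 5 (Ctrl2) swaps, while a difference between the control sets in splicing or in how their reads were counted stays open.

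The words enriched in lower transcripts had t of -8.152 for GAACGAA in the DRAP1 knockdown, -16.498 for GAGCCTG in ESRRA, -17.008 for GAGCCTA in PPARD and -15.136 for AGAGTTC in YY1, against lowest shuffled values of -5.11, -5.19, -5.10 and -4.98. A candidate explanation is that each siRNA guide, through the bases of its seed, also lowered transcripts with matching 3′ UTRs; under a guide cut from the targeted gene, each word should lie in that gene, and it did (value 1 for each of the 4), although 8.96%, 14.7%, 21.0% and 37.5% of all tested words lie in DRAP1, ESRRA, PPARD and YY1. With genes split by chromosome, the DRAP1 word was lowest on odd chromosomes (t of -6.19) but not on even ones (-4.98, with ACCGGAA lowest). ACCGGAA had t of 0.79 on odd chromosomes. GAGCCTG for ESRRA (-12.6 odd, -10.4 even) and GAGCCTA for PPARD (-12.0 and -11.1) were lowest in both parts. For YY1, AGAGTTC was lowest on odd chromosomes (-9.37 on even) and GAGTTCA, its partner, on even ones (-8.71 on odd). The siRNA sequences were not in the sources used here, so the guides themselves were not compared. Similar seeds in the ESRRA and PPARD siRNAs are argued against as the main cause of the correlation of these knockdowns over all genes searched. There r without genes carrying GAGCCT was 0.934 times r over all of them. Most of these genes were uncalled, so the test could not decide for the 63 main transcripts lower in both, where similar seeds stay open. GAGCCTA had t of -3.20 in the ESRRA knockdown and GAGCCTG -2.85 in the PPARD knockdown. In the DRAP1 and YY1 knockdowns both words had positive t. The negative values lay within the range of the shuffles, but that range is the extreme over all words searched. It could therefore not decide for single words fixed by the other knockdown, and an effect of either word in the other knockdown stays open. Direct effects of losing each factor stay open for the lower transcripts with a word, as do its effects on the many without it.

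Higher DICER1 and HMGA2, both known targets of the let-7 microRNA, raised the hypothesis that let-7 repression was relieved more by the targeting siRNAs than by the siRNA of the controls. In the DRAP1 and YY1 knockdowns genes with the let-7 site CTACCTC did lie higher (t of 3.743 and 3.671, rank 3 of 16162 and 5 of 16156 words), but both values lay under the highest of the shuffles over all words (4.79 and 4.60), and the miR-29 site TGGTGCT ranked above let-7 in the DRAP1 knockdown (3.83, rank 2). The values for ESRRA and PPARD, 0.923 and 1.497 (rank 3798 of 16159 and 1639 of 16156), argue against it in the knockdowns where HMGA2 rose by 1.64 and 1.27 in the authors' deposited tables. In the YY1 knockdown let-7 ranked above the other microRNA sites searched (next miR-29, 2.99, rank 50). In ESRRA and PPARD others ranked above let-7, with miR-27 at 3.29 (rank 38) and miR-21 at 3.53 (rank 18). Also high were miR-21 in ESRRA (3.28, rank 41) and, in PPARD, miR-29 (3.14, rank 51) and miR-199a-3p (3.05, rank 65). These values lay under the highest of the shuffles (4.95 and 4.97), and other sites lay low, such as miR-24 at -2.88 and -1.36. Whether microRNA sites as a set lay higher was not tested. Relief of let-7 stays open for DRAP1 and YY1, and the higher DICER1 stays unexplained in all 4.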
